A study of Mus musculus with 12 samples.

How the data were processed

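ATAC-seq libraries were made from about 25000 bead-bound hepatocyte nuclei per reaction, transposed for 30 min at 37 °C and amplified in 12 PCR cycles, per the labels' protocols, and sequenced as paired ends. The submitters' processing notes name BWA 0.7.5a-r405, SAMtools, HOMER, DESeq2 and the mouse build mm10, without saying which step each served. Whether reads were shifted for the transposase offset, how duplicates and reads with several matches were treated and how peaks were called are not given in the sources used here. Reads that match several places matter most at repeats, and counts in fixed 200 bp windows of a merged peak set are the same windows in every library.

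The authors deposited a table of 52530 merged peaks with, per the file headers, their annotation and the nearest gene. Its signal columns hold reads per peak for 12 libraries, which the authors had normalized by 1 size factor per library before they were deposited. In each of these columns all values were whole multiples of a single step (100% within 1e-06 reads), which is the pattern of reads divided by 1 factor per library, and the depths given here come from that step. Those depths and reads per peak take the step as 1 read. Count models were not used, because in most columns the smallest value above 0 is more than 1 step, so the step could not be read off directly as a single read. The authors also deposited log2 fold changes and adjusted p-values of fasted against fed within fresh and within frozen tissue. The method behind these p-values is not given in the file, and they are quoted only as the authors' deposited table. All columns of per-library values were used.

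The labels name 6 mice by number, each with a fresh and a frozen library, but the columns carry letters A to C within each group, which match no mouse number. Columns with the same letter and feeding state deviated from their group means together, with r from 0.329 to 0.640 for the 6 pairs, and each correlated best with its own letter (highest other r = 0.0213). All 6 exceeded 0.1, the value set for treating letters as pairs, so columns of one letter were averaged as 1 mouse. The pairing therefore comes from the data and not from a label.

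Values were transformed as log2(value + 1) without a filter and fitted with limma 3.58.1 in R 4.3.3 (trended prior, two-sided, Benjamini-Hochberg adjustment over all peaks, threshold 0.05). Fasting was tested on the mean of the fresh and frozen library of each letter, 3 against 3, and again within each preparation. Freezing was tested over all 12 libraries with feeding state as a covariate, and the difference of the fasting effect between preparations as an interaction. Peaks annotated to each of 24 gene lists were tested with camera at a preset correlation of 0.01 and with an estimated one. The lists were also tested with fry, which asks whether a list changes by itself and not against the other peaks. The lists cover gluconeogenesis, fatty acid oxidation and ketogenesis, lipogenesis, cholesterol synthesis, glycolysis and glycogen, glucocorticoid receptor, cAMP and CREB, insulin and FOXO1, growth hormone and STAT5 targets, amino acid catabolism, circadian clock, bile acid, autophagy and lysosome, xenobiotic, acute phase, immediate early, heat shock and reticulum stress genes, hepatocyte identity, and markers of macrophages, endothelium, stellate cells, bile duct cells and lymphocytes. A peak counts for the nearest gene as annotated, which need not be the gene it regulates. The tests, lists and naming rule were fixed before the data were examined.

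Peaks were named by rule. For the average fasting comparison and for freezing these were the 5 higher and 5 lower peaks with the largest log2 difference among called peaks with no overlap between groups and a mean above the median, with 1 peak per gene. For fresh and frozen liver alone, 3 were taken each way. For each list up to 3 genes were named, each by its peak of lowest p, and 20 fasting genes were fixed by the peak nearest to their start whether called or not. Not all peaks chosen by these rules are given in the text.

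On simulated data with 200 of 52530 peaks changed, the average fasting test found 42% of peaks changed 1.25-fold, 86% at 1.5-fold and 98% at 2-fold, with 5 false calls. The fresh test found 72% and the frozen test 42% at 1.5-fold, and the freezing test 94%. These libraries were drawn independently, with 1 dispersion of 0.00496 for all peaks and no effect of the mouse. In the data the 2 libraries of a letter deviated together, and 34.6% of peaks were called for fasting. The shares found therefore hold for the simulated setting and may differ in the data. With 4 of 24 lists shifted by 0.5 on the log2 scale in simulated independent peaks, camera found 4, and called 1 of the 20 others. The shallowest library had 51 reads in its median peak, a counting error of 14.0%, and the deepest 217 reads, an error of 6.79%. These cover counting error only, since PCR copies are not independent molecules.

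Alternatives were quantile normalization, rescaling to the same median, to total reads or to the near peaks, a filter on the lowest 25% of peaks, a pseudocount of 8, robust limma, a minimum log2 difference of 1, near or distant peaks alone, each letter left out, the letter as a block and other pairings of the columns. The planned comparison of sequence motifs was not run, since no genome sequence was used here. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.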

Results

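Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts and tags open DNA, in hepatocyte nuclei of 6 female HEP-INTACT mice. INTACT tags the nuclei of one cell type genetically so that they can be pulled from the whole liver on beads. Livers were taken from 3 mice fasted for 16 h from ZT12, the start of the active phase, and from 3 mice with free access to food, killed at the same time of day. Each mouse gave a library from fresh and a library from frozen liver, which made 12 libraries in 4 groups of 3. In units of 1e+06 reads in peaks, the libraries held between 3.69 and 14.5, with 51 to 217 reads in the median peak. In the same units fresh fed libraries held 8.70 ± 2.85 (SD, n = 3), fresh fasted 10.9 ± 3.84, frozen fed 6.86 ± 2.01 and frozen fasted 7.25 ± 3.09. Of the peaks 18534 lay within 1 kb of a gene start and 33996 beyond. Introns held 38.2% of the peaks, promoters 27.9% and intergenic DNA 26.9%. Positions are on mm10, and each peak is listed as 200 bp. Log2 differences are of log2(normalized reads + 1), given with the standard error (SE), and understate the change of low peaks.

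The first comparison was of hepatocyte chromatin in fasted against fed mice. Averaged over both preparations, more peaks were higher than lower at genes of fatty acid oxidation and ketone production (104 and 23 of 245), and more were lower than higher at genes of fat synthesis (77 and 30 of 187) and cholesterol synthesis (60 and 17 of 139). The other peaks of these genes were not called, and none of these lists passed the list test with an estimated correlation. The promoter of Fgf21, a hormone made by the fasting liver, rose from 44.4 ± 6.50 to 176 ± 14.5 normalized reads (SD, n = 3 mice each; chromosome 7, 45615398 to 45615598), a log2 difference of 1.97 ± 0.14. A promoter peak of Srebf1, the main activator of fat synthesis genes, fell from 136 ± 17.2 to 26.8 ± 1.19 reads (chromosome 11, 60222409 to 60222609), a log2 difference of -2.29 ± 0.15. In all, 8678 peaks were higher and 9485 lower in fasted mice by limma, 34.6% of those tested (adjusted p under 0.05, two-sided). Among them 806 were higher and 2953 lower by more than 1 on the log2 scale. The balance depends on the peaks and the scale: without the lowest 25% of peaks 6470 were higher and 5310 lower, and with libraries scaled to the same median over peaks near gene starts 4056 and 12857. All 6 fasted libraries lay on the same side of all 6 fed libraries at 6802 peaks, or 12.9%. Leaving out both libraries with the letter B of the fed mice lowered the count from 18163 to 11500.

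**Figure D1:**
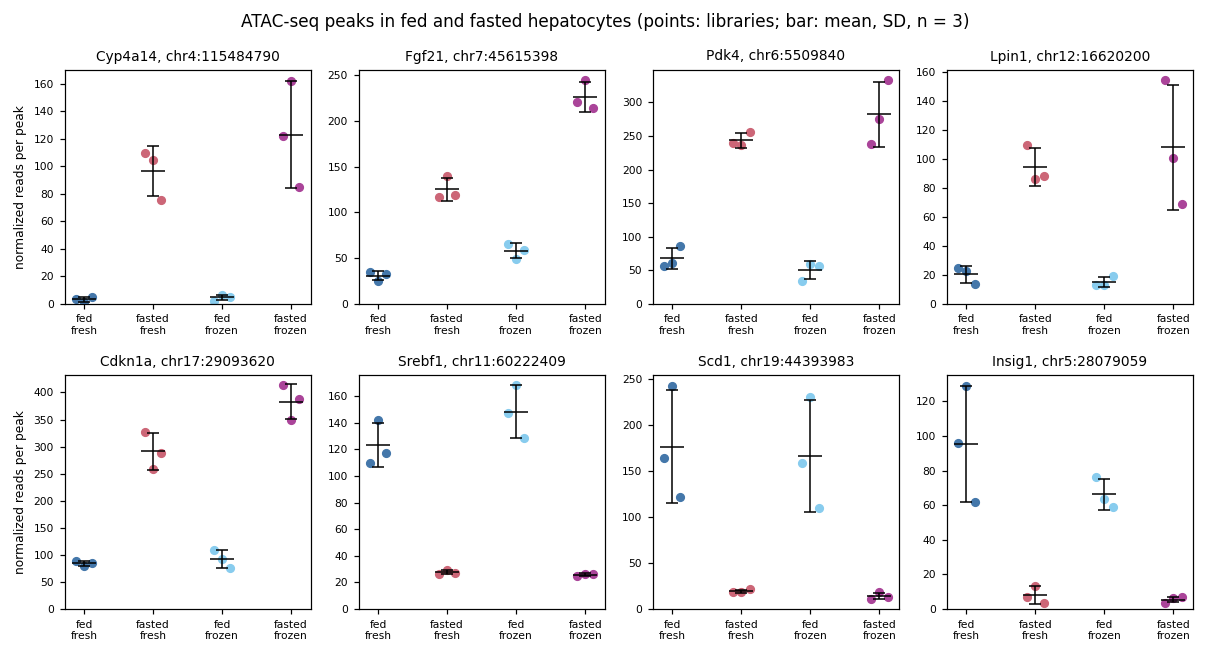
Normalized reads per peak (vertical axes, from 0) at 8 peaks in each of the 4 groups (horizontal axes); points are libraries, bars the mean and SD of 3. The peaks at Cyp4a14, Fgf21, Pdk4, Lpin1 and Cdkn1a were higher in fasted than in fed libraries of the same preparation, and those at Srebf1, Scd1 and Insig1 were lower.

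The list of fatty acid oxidation and ketogenesis genes had 104 higher and 23 lower peaks of 245 (119 and 27 when adjusted over the list alone). The peak of lowest p at Cyp4a14, a fatty acid hydroxylase gene, lay 11.3 kb from its start (chromosome 4, 115484790 to 115484990, intergenic) and rose from 3.91 ± 0.983 to 110 ± 27.1 reads. Its fed value was close to the floor, so the fold is uncertain. The Cyp4a14 promoter rose by 1.94 ± 0.15. Pdk4, which encodes a kinase that restrains glucose oxidation, had 7 higher and 3 lower peaks of 10, and its intergenic peak at chromosome 6, 5509840 to 5510040, rose by 2.18 ± 0.16. Angptl4, an inhibitor of lipoprotein lipase, had 9 higher peaks of 11, among them its promoter at 1.51 ± 0.26, but a peak in exon 1 (chromosome 17, 33781173 to 33781373) fell, with a log2 difference of -1.73 ± 0.14. Cpt1a, central to fat oxidation, had 5 higher peaks and 1 lower of 11, but its promoter at 0.14 ± 0.05 did not pass the test (adjusted p = 0.0669 by limma).

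Peaks given for genes of the lists are those of lowest p of their gene, unless they are among the promoter peaks fixed in advance. Lipogenesis genes had 30 higher and 77 lower peaks of 187 (34 and 87 adjusted over the list alone). At Srebf1 13 of 15 peaks fell and at Scd1, a desaturase gene, 10 of 11. The Scd1 peak of lowest p, near its transcript end (chromosome 19, 44393983 to 44394183), dropped to 16.8 ± 1.90 from 172 ± 61.0 reads. The Fasn promoter had a log2 difference of -0.52 ± 0.08. Cholesterol synthesis genes had 17 higher and 60 lower peaks of 139 (18 and 68 adjusted over the list alone). Insig1, a sterol-sensing regulator, had 11 lower and 3 higher peaks of 24, with a log2 difference of -3.47 ± 0.30 at its peak of lowest p (chromosome 5, 28079059 to 28079259).

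Targets of the glucocorticoid receptor had 107 higher and 20 lower peaks of 265 (113 and 21 adjusted over the list alone). Klf9 alone held 21 of the higher peaks. Nr3c1, the gene of the receptor itself, is on the list and held 13 of the lower ones. The promoter of Cdkn1a, a cell cycle inhibitor, rose by 1.91 ± 0.10, and an intergenic peak 9.33 kb from Lpin1 rose by 2.45 ± 0.21, while the promoters of Tat and Fkbp5 at 0.08 ± 0.08 and 0.08 ± 0.06 did not pass the test. Immediate early genes had 43 higher and 17 lower peaks of 135 (48 and 18 adjusted over the list alone), with 1.52 ± 0.17 at a peak near Fos. Ier5 of this list went the other way, with 2 lower and 0 higher peaks of 3. These 5 lists passed camera with a preset correlation of 0.01, at adjusted p = 1.81e-06 for fatty acid oxidation and for cholesterol synthesis, 0.000263 for lipogenesis, 1.79e-05 for glucocorticoid receptor targets and 0.00984 for immediate early genes. Among peaks beyond 1 kb of a gene start lipogenesis and cholesterol synthesis no longer passed. With an estimated correlation none of the 24 lists passed, the lowest adjusted p = 0.433 being that of fatty acid oxidation and of immediate early genes. By fry, fatty acid oxidation and immediate early genes passed (adjusted p = 0.00518 each). So did heat shock genes (adjusted p = 0.00768 by fry), lipogenesis and cholesterol synthesis (0.0174 each). Glucocorticoid receptor targets did not pass fry (adjusted p = 0.0523), nor did the other lists. Other splits of the same mice gave up to 6 passing lists with the preset correlation. Each of them still puts more fasted mice on one side, so they cannot show how many lists pass without a fasting difference. Since none of the 24 lists passed with an estimated correlation, the list tests carry less weight than the counts of peaks.

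**Figure D2:**
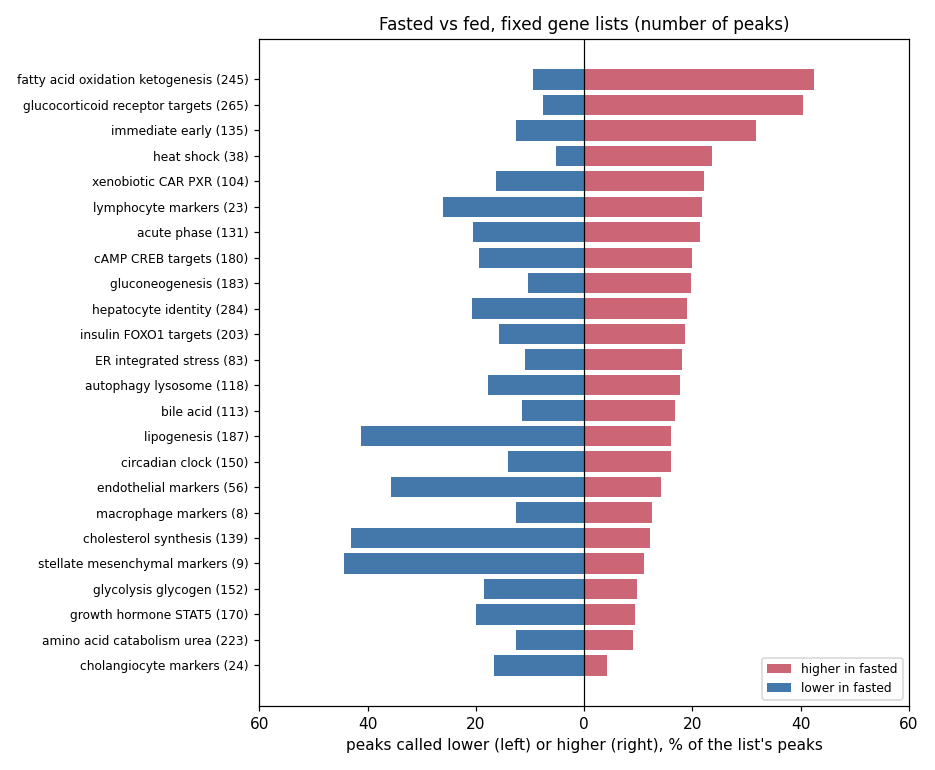
Share of the peaks of each of the 24 fixed gene lists (vertical axis, with the number of peaks) that were called higher (right) or lower (left) in fasted than in fed mice, in percent of the list's peaks. Fatty acid oxidation had 104 higher of 245 peaks and cholesterol synthesis 60 lower of 139.

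The remaining lists did not pass camera. Gluconeogenesis genes had 36 higher and 19 lower peaks of 183: the Pck1 promoter rose by 0.31 ± 0.09, and that of G6pc at 0.17 ± 0.08 did not pass. Targets of growth hormone and STAT5 had 16 higher and 34 lower peaks of 170, and Cish, a STAT5 feedback gene, had 6 lower of 9. Hepatocyte identity genes had 54 higher and 59 lower peaks of 284. Foxa2, a liver transcription factor, had 12 lower of 28, while Foxa1 had 6 higher and 2 lower of 12 and Alb 8 and 1 of 16. On the glycolysis and glycogen list, Pklr had 3 lower peaks of 4, but its promoter at -0.05 ± 0.06 did not pass. Higher and lower peaks numbered 15 and 28 of 152 for glycolysis and glycogen, and 36 and 35 of 180 for cAMP and CREB targets. They numbered 38 and 32 of 203 for insulin and FOXO1 targets, 20 and 28 of 223 for amino acid catabolism and 24 and 21 of 150 for circadian clock genes. Bile acid genes had 19 and 13 of 113, autophagy and lysosome genes 21 and 21 of 118, xenobiotic genes 23 and 17 of 104 and acute phase genes 28 and 27 of 131. Heat shock genes had 9 and 2 of 38, and genes of the endoplasmic reticulum stress response 15 and 9 of 83. Among markers of other liver cells, higher and lower peaks numbered 8 and 20 of 56 for endothelium, 1 and 4 of 9 for stellate cells, 1 and 1 of 8 for macrophages, 1 and 4 of 24 for bile duct cells and 5 and 6 of 23 for lymphocytes.

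Largest by the naming rule among higher peaks were those nearest to Gm28856 at 2.96 ± 0.50, Cbfa2t3 at 2.47 ± 0.15, Sik1, a kinase gene induced by cAMP, at 2.20 ± 0.19, Cdkn2aipnl at 2.20 ± 0.15 and Pdk4. Among lower peaks they were those nearest to Shcbp1 at -3.87 ± 0.16 (chromosome 8, 4839177 to 4839377, intergenic), Gm13547 at -3.61 ± 0.18 (chromosome 2, 29737636 to 29737836, intron 23), Platr26 at -3.32 ± 0.32, Acot7 at -2.72 ± 0.17 and Mir6392 at -2.67 ± 0.15. Their adjusted p by limma lay between 1.37e-05 and 0.00213.

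Peaks within 1 kb of a gene start and more distant peaks moved apart. Near gene starts 3643 peaks were higher and 851 lower, and beyond 1 kb 5035 were higher and 8634 lower. The median log2 difference was 0.12 near and -0.05 beyond. Peaks near gene starts held 44.6% ± 0.19 (SD, n = 3) of the normalized reads in fresh fed, 47.6% ± 0.55 in fresh fasted, 46.4% ± 0.78 in frozen fed and 48.9% ± 0.51 in frozen fasted libraries. The direction depends on the scale: with libraries scaled to the same median over the near peaks, 1195 of them were higher and 1600 lower, and beyond 1 kb 2861 were higher and 11257 lower.

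The fasting comparison was repeated within each preparation. In fresh liver 6003 peaks were higher and 8474 lower in fasted mice, and in frozen liver 6717 and 7861. Scaled to the near peaks they were 2947 and 11857 in fresh and 3430 and 10582 in frozen liver, and without the lowest 25% of peaks the frozen counts were 5187 and 4495. The peak near Shcbp1 had a log2 difference of -3.30 ± 0.19 in fresh and -4.43 ± 0.21 in frozen liver, the peak nearest to Gm13547 -3.52 ± 0.17 and -3.70 ± 0.21, and that nearest to Platr26 -2.82 ± 0.25 and -3.82 ± 0.36. Cbfa2t3 rose by 2.15 ± 0.18 in fresh and 2.79 ± 0.17 in frozen liver, Gm28856 by 2.73 ± 0.42 and 3.19 ± 0.50, Cdkn2aipnl by 2.14 ± 0.16 in fresh and Pdk4 by 2.50 ± 0.20 in frozen. Higher in both were 3706 peaks, where independent lists would share 768, and lower in both 6367, where they would share 1268. Opposite directions occurred at 2 peaks. Across peaks, which are not independent replicates, the log2 differences of both preparations had r = 0.919 and a covariance of 0.269. The other 9 splits of the lettered pairs gave r from 0.585 to 0.804 and covariances from 0.0228 to 0.0730. Both preparations share their mice, and each of these splits still puts more fasted letters on one side. Their values therefore hold part of the fasting difference and are not a baseline without it. The authors' deposited table lists 12111 peaks with adjusted p under 0.05 in fresh and 15482 in frozen liver. Of these 11935 and 13968 were also called by limma, all in the same direction. Without the fed B library the frozen count fell to 8711.

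**Figure D3:**
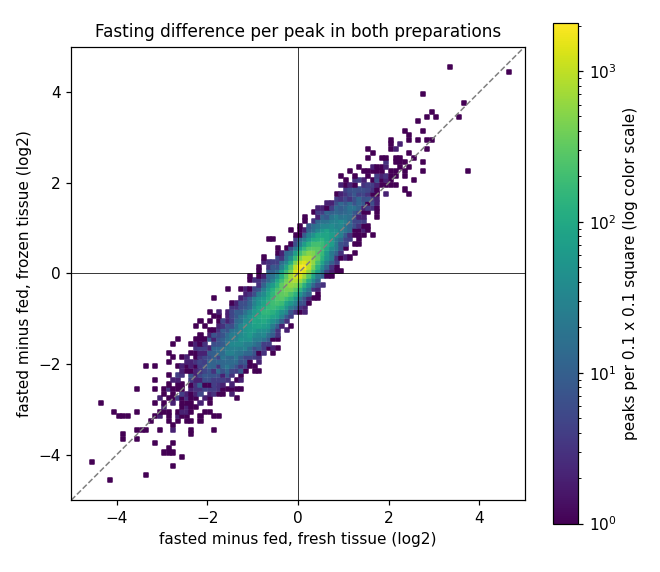
Fasted minus fed log2 difference of each peak in fresh (horizontal) and frozen liver (vertical), as the number of peaks per square on a log color scale; the dashed line marks equal values. Points follow the diagonal, with r = 0.919 across peaks.

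Whether fasting acted differently in the 2 preparations was tested as an interaction. No peak passed limma, and 2702 peaks had an unadjusted p under 0.05. With the column letter as a block, which compares differences within lettered pairs, the count was also 0, with 5983 at an unadjusted p under 0.05. For the peak near Shcbp1 the difference between the preparations was -1.13 ± 0.28 (adjusted p = 0.781 by limma). In simulated data with independent libraries and few changed peaks this test found 90% of peaks changed 2-fold and 14% of those changed 1.5-fold. Among the 18163 peaks called in the average, 73.5% had a larger difference in frozen liver, with a median ratio of frozen to fresh of 1.24, but after quantile normalization the ratio turned to 0.928.

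Freezing itself was compared over all 12 libraries, with feeding state in the model. Peaks at repeats of ribosomal RNA and satellite DNA stood at the top among those higher in frozen liver. The largest were an intronic peak nearest to Txndc11 at 3.25 ± 0.18 (chromosome 16, 11144009 to 11144209), one nearest to Filip1l at 2.81 ± 0.12, one nearest to Axin2 at 2.54 ± 0.14 and one nearest to Pex2 at 2.46 ± 0.13. These 4 are annotated as LSU rRNA repeats, and an intergenic peak nearest to Lrrc4c, 1199 kb away, at 2.84 ± 0.49, as a major satellite. Of 23 peaks in rRNA repeats 22 were higher in frozen liver, with a median of 2.01, and of 26 in satellites 20 were higher and 3 lower, with a median of 1.22. Of 55 peaks in tRNA repeats 31 were higher and 1 lower, with a median of 0.31. LTR, SINE and LINE repeats had medians of -0.17, -0.12 and -0.15, against -0.11 over all peaks beyond 1 kb of a gene start. Lower in frozen liver were the promoters of Rad18, a DNA repair gene, at -1.78 ± 0.11, Zfp418 at -1.68 ± 0.08, Tmem231 at -1.60 ± 0.11 and Hnf4g at -1.57 ± 0.09, and an intronic peak of Tpd52 at -1.58 ± 0.08. In all, 15093 peaks were higher and 17223 lower in frozen than in fresh libraries by limma, of which 1005 and 1757 differed by more than 1 on the log2 scale. The balance depends on the peaks and the scale: without the lowest 25% of peaks 14186 were higher and 10716 lower, and with libraries scaled to the near peaks 12634 and 20202. At 14105 peaks, or 26.9%, the 6 frozen and the 6 fresh libraries did not overlap.

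Many gene lists were higher in frozen liver. Values also spread wider over peaks in frozen libraries, with a mean SD of log2 values of 1.02 in fed and 1.19 in fasted mice. In fresh libraries it was 0.869 and 0.955. The lists were not tested after quantile normalization, so whether the wider spread gives part of their rise was not tested. Circadian clock genes had 70 higher and 25 lower peaks of 150 (72 and 25 adjusted over the list alone), with 1.39 ± 0.07 in an intron of Per2 and 1.14 ± 0.06 at the promoter of Nr1d1, both clock repressors. Immediate early genes had 64 and 19 of 135, with 1.14 ± 0.05 at the promoter of Atf3 and 0.99 ± 0.05 in Jund. Glucocorticoid receptor targets had 117 and 21 of 265, with 1.57 ± 0.06 at the promoter of Dusp1, a phosphatase gene. Hepatocyte identity genes had 101 and 51 of 284, with 1.31 ± 0.08 at the promoter of albumin, Alb. Higher and lower peaks numbered 76 and 17 of 183 for gluconeogenesis, 100 and 28 of 245 for fatty acid oxidation, 78 and 20 of 187 for lipogenesis, 62 and 30 of 152 for glycolysis and 74 and 34 of 180 for cAMP targets. They numbered 74 and 40 of 203 for insulin targets, 100 and 20 of 223 for amino acid catabolism, 54 and 12 of 113 for bile acid, 52 and 16 of 104 for xenobiotic, 60 and 24 of 170 for growth hormone and 58 and 17 of 131 for acute phase genes. Reticulum stress genes had 37 and 12 of 83 and heat shock genes 17 and 8 of 38, but among peaks beyond 1 kb of a gene start 2 heat shock peaks were higher and 4 lower, and that list no longer passed (adjusted p = 0.960 by camera), nor did insulin and FOXO1 targets, which left 15 lists. These 17 lists passed camera with the preset correlation. With an estimated correlation 2 did, the clock genes (adjusted p = 0.00888) and the reticulum stress genes (adjusted p = 0.0494). Cholesterol synthesis, with 26 and 37 of 139, and autophagy, with 40 and 29 of 118, did not pass. Markers of other liver cells did not pass camera either. Endothelium had 9 higher and 25 lower of 56, bile duct cells 4 and 12 of 24 and stellate cells 1 and 5 of 9. Macrophages had 1 and 3 of 8 and lymphocytes 6 and 5 of 23. Single peaks at markers of these cells fell, with -1.25 ± 0.07 at the promoter of Pkhd1, a bile duct gene, and -1.54 ± 0.14 in Lhx2, a stellate cell gene. With fry all lists passed except cholesterol synthesis, macrophage markers and lymphocyte markers. Bile duct (adjusted p = 3.17e-06 by fry), stellate (0.000126) and endothelial markers (0.000368) passed with negative medians, and autophagy genes (0.000194) with a positive one. Fry does not compare a list with the other peaks, most of which were also called.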

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

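In this part the tests of background DNA and of dynamic range were chosen only after the results were seen.

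The fasting response of 3 gene lists differed between frozen and fresh liver in a test of the difference itself, camera on the interaction, with the preset correlation but not with an estimated one (adjusted p = 0.323, 0.564 and 0.172 in the order below). Frozen minus fresh, the response was shifted upward for fatty acid oxidation genes (adjusted p = 0.000609, median difference 0.08 on the log2 scale), downward for cholesterol synthesis genes (adjusted p = 0.000162, median -0.10), and upward for bile acid genes (adjusted p = 0.00702, median 0.07). None of the 3 lists passed fry (adjusted p = 0.303, 0.718 and 0.140 in the same order). No single peak passed the interaction test when adjusted over all peaks. Adjusted over the list alone, 1 peak of cholesterol synthesis genes was higher and 13 lower, and 1 of fatty acid oxidation genes was higher. With the letter as a block, which pairs the libraries, the adjusted p were 0.00277, 0.00391 and 0.00507 with the preset correlation. In 2 of the 10 splits of the 6 letters, the real one included, at least 3 lists passed, and the highest other split gave 6. So few splits cannot give a share under 0.05. The other splits also keep more fasted letters on one side, so they are not splits without a fasting difference.

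Across peaks, fasting differences were also larger in frozen liver. Whether the 3 lists share a cause with this was not tested, and the median of the bile acid list turned from -0.01 in fresh to 0.08 in frozen liver. After quantile normalization, which gives every library the same spread of values, the median ratio of frozen to fresh differences fell from 1.24 to 0.928 (0.916 to 0.950 with each letter left out). A larger dynamic range of the frozen libraries may therefore account for the pattern across peaks. A choice of peaks on noisier frozen values does not explain it alone, because peaks chosen in 1 fasted and 1 fed letter and measured in the other letters gave ratios from 1.12 to 1.19 in all 9 choices. Freezing is a handling step applied to the same livers, and no biological explanation was tested.

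Ribosomal RNA and satellite repeats topped the peaks higher in frozen liver. Background DNA captured from the whole genome would flatten the frozen libraries, but the spread of log2 values over peaks was larger in frozen for 6 of 6 letters, by 0.194 on average (lowest 0.135). Within groups, rRNA peaks on different chromosomes deviated together, with a mean r of 0.527, against at most 0.131 in 1000 random peak sets matched on mean value. That is consistent with reads of a multi-copy repeat being spread over few assembled copies, so these peaks may report the amount of such reads rather than their own loci. No biological explanation was tested.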

How the results depend on the processing

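The scalings to total reads and to the near peaks, the 36 pairings and the lists on distant peaks alone were chosen after seeing the data. Every alternative here called peaks in both directions for the 4 comparisons of peaks with calls. The average fasting count of 18163 became 11780 without the lowest 25% of peaks (6470 higher, 5310 lower), 3759 above a log2 difference of 1 and 5499 among near peaks alone, and ranged from 11500 to 17672 with a letter left out. For fresh liver the same settings gave 8671, 3170 and 3775 (range 9747 to 14642), and for frozen liver 9682 (5187 higher, 4495 lower), 4591 and 3524 (range 8711 to 14001), against 14477 and 14578. Freezing gave 14186 higher and 10716 lower without the lowest 25%, from 15093 and 17223. It gave 2762 above a difference of 1, 12612 near and 19694 distant peaks (range 29530 to 32767), against 32316. The filters and peak classes test fewer peaks, and a left-out letter leaves fewer mice. The interaction called 4 peaks among near peaks alone, 0 in the other settings and 0 with each letter left out. The cause of the 4 was not tested.

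Scaling to the near peaks moved the fasting median from 0.05 to -0.08 and the calls to 4056 higher and 12857 lower, from 8678 and 9485. In fresh liver they were 2947 and 11857, from 6003 and 8474, and in frozen liver 3430 and 10582, from 6717 and 7861. For freezing they were 12634 and 20202, and scaled to total reads 13194 and 19599. With the letter as a replicate block the counts were 20336 for fasting, 36805 for freezing, 0 for the interaction and 17 lists for freezing. Under every one of the 36 pairings of fresh and frozen columns 17908 peaks were called, with counts from 18163 to 28051.

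For fasting, 0 lists passed with an estimated correlation and 3 among distant peaks, where lipogenesis and cholesterol synthesis no longer passed, against 5, with 5 to 6 when a letter was left out. For freezing 2 passed with an estimated correlation and 15 among distant peaks, against 17. The heat shock list turned in freezing among distant peaks, with a mean of -0.0293 relative to the other peaks (adjusted p = 0.960), and the cause was not tested. Of 3133 alternative values of named peaks 46 lost and 6 gained a call and 2 changed sign, neither called. Of 360 for lists 23 lost and 5 gained a call with their sign kept. Another 22 changed sign, 1 of which, heat shock, lost its call as well. Motif alternatives were not run.

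Other splits of the 6 letters called at most 0 peaks for fasting on average (real 18163), in fresh (14477) and in frozen liver (14578), 0 for the interaction (real 0) and 6 lists (real 5), and 1, 1, 1, 10 and 4 of the 10 splits reached the real count. So few splits cannot give a share under 0.05. The other splits also mix fed and fasted letters on both sides, so a fasting difference widens the spread within their groups. Their counts of 0 for fasting are therefore not a measure of false calls. They keep more fasted letters on one side, so the 6 lists may hold part of the fasting difference. For freezing 1 of 100 splits of the libraries, which ignore the pairs, and 1 of the 32 splits that part the lettered pairs reached 32316. The highest others gave 9966 and 0. The split with 9966 still had 5 of the 6 frozen libraries on one side. Both shares are under 0.05, but 32 splits cannot give a share below 1 in 32. In the numbering of the titles all fresh libraries come before all frozen ones. A batch of library making, if there was one, cannot be told apart from freezing by these splits. For the lists in freezing 3 of 100 splits reached 17, the highest other also giving 17 and the median of the others 5. Small changes are missed most: at 1.5-fold the frozen test found 42% of simulated changes and the interaction 14%.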

Other observations

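The counts per gene, the 3 tests of the promoter gap and the tests of repeats in this part were chosen only after the results were seen. Some genes gathered many changed peaks. Klf9, a transcription factor gene induced by glucocorticoids, had 21 higher and 0 lower peaks of 30 in fasted mice, and Ptpn1, which encodes a phosphatase that acts on the insulin receptor, 18 and 0 of 30. Pim3 had 14 higher and 1 lower of 25, Rasgef1b 14 and 3 of 20, Nfia 13 and 2 of 38 and Rreb1 13 and 2 of 49. Tbl1xr1 had 11 higher and 5 lower of 30 and Tsku 11 and 1 of 15. In the other direction Slc6a6, the taurine transporter gene, had 15 lower and 0 higher peaks of 23, and 4930542M03Rik 14 and 0 of 18. Gm17746 had 12 lower and 5 higher of 30, Sh3pxd2a 12 and 0 of 19 and Dhrs3 11 and 4 of 32. Nr3c1, which encodes the glucocorticoid receptor itself, had 13 lower and 0 higher of 33, Srebf1 13 and 0 of 15, and Foxa2 12 and 0 of 28. The peaks of Klf9 and Nr3c1 are among those counted above for glucocorticoid receptor targets, so they are not separate evidence.

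Promoter and distal peaks parted in fasting, with a gap of 0.17 ± 0.02 (SE over letters) between their median log2 differences. Depth does not account for it: the slope of the near-peak share within groups, taken 2 standard errors wide, moves it by at most 0.150 percentage points in either direction, against the rise of 2.75 seen. Nor does a higher contrast between high and low peaks account for all of it, because within 20 bins of mean value the gap was 0.221 ± 0.04. After quantile normalization, which gives every library the same spread of values, the gap was 0.129 ± 0.03. That does not settle whether normalization or contrast gives part of it. Freezing, a handling step on the same livers, also parted near and distant peaks, with median log2 differences of 0.06 and -0.11. Near gene starts 6974 peaks were higher and 5139 lower in frozen liver, and beyond 1 kb 8119 and 12084. A gap in this direction is therefore not particular to fasting. For the fasting gap a difference of fasted and fed chromatin stays open, untested beyond this.

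Peaks in RMER1 and RMER19B, families of rodent repeats, were often lower in fasted mice, while the 2 other RMER families counted, which were not tested against these, had fewer lower than higher peaks: RMER15 had 10 lower and 14 higher of 53, and RMER10A 6 and 8 of 27. Of 54 repeat families with at least 20 distal peaks, Fisher's exact test against other distal repeats passed for RMER1B (41 of 76 lower, adjusted p = 1.01e-05), RMER19B (40 of 75, adjusted p = 1.01e-05) and RMER1A (22 of 42, adjusted p = 0.00470). Of all 200 distal peaks in RMER1 and RMER19B repeats 53.0% were lower and 15 peaks were higher. In 1000 random sets of other distal repeats matched on mean value at most 33.0% were lower, so position and level alone do not account for the share. The families were picked for their lower peaks in these same data, so the random sets are not separate evidence for them. Copies were counted as independent peaks. Whether they deviate together within groups, as rRNA peaks did, was not tested. These copies may share a sequence that loses a binding factor in fasting, a hypothesis that was not tested here without a genome sequence.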
